A study of Mus musculus with 4 samples.

How the data were processed

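Whole lungs of mice with an edited Galt gene (GAL) and of wild-type mice (WT) had been rinsed of blood, minced and digested with collagenase and DNase, and the freed cells had been taken into droplets with barcoded beads (SeekOne Digital Droplet kit), per the labels. Sequencing was paired-end with reads of 150 nt. The submitters' processing notes name fastp, STAR and Seurat without versions, and the mouse genome under its names GRCm38 and mm10; the gene annotation used for counting is not given in the sources used here. The values used were the raw UMI counts per gene and barcode that the authors deposited as whole numbers, in 1 matrix per library with 32285 genes. The lowest barcode of every library held 500 UMIs, so barcodes below that total had been removed before deposit. Digestion frees some cell types better than others, so the shares below are of recovered cells.

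Cells with at least 500 UMIs, at least 300 genes and at most 20% of UMIs from mitochondrial genes were kept. Doublets were scored by Scrublet in each library, with an expected rate of 0.8% per 1000 cells. The automatic threshold removed 0%, 2.38%, 2.75% and 5.29% of the cells of GAL replicate 1, GAL replicate 2, WT replicate 1 and WT replicate 2, so the cells with the highest scores were instead removed up to the expected rate in all 4 libraries; this rule was set after those values were seen. Counts of kept cells were scaled to 10000 per cell and log-transformed, 2000 variable genes were reduced to 40 principal components, and cells were grouped by Leiden clustering at resolution 1.0 on a graph of 20 shared neighbours. Mitochondrial, ribosomal, sex-linked and antigen receptor segment genes and Galt took no part in clustering. No correction for differences between libraries was made.

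Clusters were named from 34 lists of cell type markers by the highest mean score. A name needed at least 3 detected markers and no larger number of another type's markers among the 10 leading genes; names were also withheld from a cluster with none of its own markers among those genes and a score within 0.5 of the next type, a rule set after the clusters were seen. Of 38 clusters, 33 were named, in 26 classes, and 5 were left unnamed. Classes are called "like" their type, since no protein or position was measured. The 22 classes with at least 30 cells in every library were tested for gene changes, and the 6 with the most cells in their smallest library are the main classes.

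Counts were summed per library, over all kept cells (whole lung) and within each class, and GAL was compared with WT by the edgeR quasi-likelihood test with filterByExpr and TMM normalization. Adjusted p-values are Benjamini-Hochberg values over the genes of 1 comparison, and a gene was called at an adjusted p under 0.05. CPM values are after TMM scaling except for Galt, where they are of all counts of the sum, and errors of log2 fold changes are standard errors. Shares of cells were tested by edgeR on cells per class with the kept cells as offset, adjusted over 26 classes. Gene lists with at least 5 measured members were tested by camera with a preset correlation of 0.01, adjusted over all lists of a comparison, and again with the correlation estimated per list and by fry. Marker lists of other cell types were tested by camera with the preset correlation in each class. Exact two-sided permutation of 4 libraries in groups of 2 cannot give a p below 0.333, so the p-values rest on the spread that edgeR pools across genes. The labels do not say how animals map to libraries, and the p-values measure the spread between these 4 samples. The labels name no pairs, so the reported fits hold no term for pairs.

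The 28 gene lists, the 34 marker lists, the tests, most alternatives and the rule for named genes were chosen before the data were examined. The lists were: Leloir and galactose metabolism; nucleotide sugars and glycosyltransferases; unfolded protein response; oxidative stress and NRF2; interferon response; NF-kB and inflammatory cytokines; immediate early genes; heat shock. Further lists were surfactant, fatty acid synthesis, cholesterol synthesis, extracellular matrix, TGF-beta response, glycolysis, nuclear oxidative phosphorylation, mitochondrial DNA transcripts, cytosolic ribosomal proteins, MHC class II, MHC class I and cell cycle. The last were endothelial activation, p53 response, hypoxia, lysosome, circadian clock, glucocorticoid response, lymphocyte effector and cytotoxicity, and macrophage lipid and tissue remodelling. Galt itself was left out of its list.

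The rule named Galt in every comparison. In the whole lung it named, of called genes with both GAL libraries on the same side of both WT libraries and a mean of at least 10 CPM, the 10 with the largest rise and the 10 with the largest fall. In main classes it named 5 in each direction with at least 20 CPM. It also named up to 4 members of each list described, those with the smallest p, and up to 15 genes called in the same direction in at least 11 of the 22 classes. Predicted gene models, antigen receptor segments and sex-linked genes took no place. The values of some list members that the rule would name are not reported here, though the list tests include them. Genes named outside the rule, chosen after their values were seen, include those of the classical monocyte-like class, to which the rule of the main classes was applied, genes called by DESeq2 or by edgeR in other classes, genes given beside them, and the genes given by their level across classes, mt-Nd3 among them.

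The tests were tried on simulated data with known changes at the measured spread. The list tests with an estimated correlation and by fry were not, so whether they can pass a list with 4 libraries is not known. In the whole lung edgeR recovered 4.48% of 2-fold, 62.7% of 4-fold and 84.8% of 8-fold changes over 16823 simulated genes; the matching shares were 7.46%, 73.1% and 87.9% in the T class, 35.8%, 85.1% and 95.5% in the general capillary endothelial class, and 19.4%, 82.1% and 87.9% in the classical monocyte class. False calls numbered 9 of 110, 7 of 120, 29 of 176 and 2 of 129. For cell shares, 4-fold changes were recovered in 8 of 60 cases at the measured coefficient of variation of 53.2%, with 0 false calls, and in 60 of 60 at one of 20%, with 4 false calls.

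Alternatives were relative log expression factors, DESeq2, no gene filter, leaving out each library, doublets kept, at most 10% mitochondrial UMIs, at least 1000 UMIs and 500 genes, sums thinned to the smallest library, genes abundant in free RNA left out, equal composition of the libraries, clustering at resolution 2.0 and adjustment over all classes together. For shares they were TMM factors, blood-borne classes left out and immune and non-immune denominators. A term for the libraries' other pairing and a separate count for the classical monocyte-like class were added after seeing the data. Tools were Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Sex-linked genes were checked, and 0 of the 4 libraries stood apart from the others. All had the pattern of females, with Xist counts from 44533 to 51340 and Ddx3y counts of at most 4. A swap of samples between the groups would therefore not show. Trajectories, variants and cell-to-cell signalling were left out.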

Results

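Lung cells of mice with an edited Galt gene (GAL) and of wild-type mice (WT) were profiled by droplet single-cell RNA sequencing, with 2 libraries per group, to ask how the edit goes with the cell types of the lung and with the genes they express. Galt encodes galactose-1-phosphate uridylyltransferase, an enzyme of the Leloir pathway that turns galactose into glucose phosphates. Total counts were 62406681 UMIs in GAL replicate 1, 56218178 in GAL replicate 2, 61340929 in WT replicate 1 and 58518235 in WT replicate 2. After filtering, 10960 and 10738 GAL cells and 12438 and 13450 WT cells remained. Median UMIs per cell were higher in GAL, at 3711 and 2837 against 2360 and 2355, as was the median share of mitochondrial UMIs, at 2.32% and 2.27% against 1.83% and 1.78%. Within groups, GAL replicate 1 and GAL replicate 2 had a correlation of log2 CPM across genes of 0.979, below the 0.992 between GAL replicate 2 and WT replicate 1 (genes are not independent replicates).

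The cells fell into 26 named classes of immune, endothelial, epithelial and stromal cells. Immune classes held 52.3% and 77.2% of the GAL cells and 79.6% and 77.4% of the WT cells, a mean of 64.7% ± 17.6 (SD, n = 2) against 78.5% ± 1.56. Endothelial, epithelial and stromal classes together held 28.3%, 14.4%, 13.4% and 15.5%, in the same order. The unnamed clusters held 13.9% ± 7.72 of GAL cells and 7.08% ± 0.128 of WT cells. Among them, cluster 9, unnamed by a rule set after the clusters were seen, held 5.01% ± 3.90 against 2.48% ± 0.607. Cluster 12, with pericyte markers among its leading genes, held 4.19% against 1.83%, and cluster 17, with hemoglobin genes and alveolar type 1 markers, held 5.57% and 1.82% against 0.289% and 1.35%.

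Galt RNA was present at like levels in both groups. Whole-lung sums held 719 and 523 Galt UMIs in GAL and 578 and 543 in WT, or 13.4 and 10.6 CPM against 11.4 and 11.4. The mean was 12.0 ± 1.94 CPM (SD, n = 2) in GAL and 11.4 ± 0.0260 in WT. The log2 fold change was 0.04 ± 0.19 (95% interval −0.44 to 0.52), with an adjusted p of 0.957. In the main classes Galt lay at −0.06 (T-like), −0.23 (B-like), −0.03 (alveolar macrophage-like), 0.58 (general capillary-like) and −0.15 (interstitial macrophage-like), and its counts were too low to test in neutrophil-like cells. Over the 10 classes in which Galt could be tested, values ran from −0.58 to 0.58 and the smallest adjusted p was 0.983. The gene, ENSMUSG00000036073, lies on chromosome 4 from 41755228 to 41758695 (GRCm38, plus strand). The labels give neither the kind of edit nor its position, so UMIs from outside the edited part check nothing about the protein or the genotype.

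Stromal, epithelial and lymphatic classes had larger mean shares in GAL, and monocyte-like, NK-like and B-like classes smaller ones, but no class passed the test of shares. Classical monocyte-like cells, the blood monocytes that enter inflamed tissue, made up 0.782% ± 0.448 (SD, n = 2) of GAL cells and 2.31% ± 0.150 of WT cells, a log2 fold change of −1.56 ± 0.87 with an adjusted p of 0.577. Lymphatic endothelial-like cells, which line the vessels that drain the tissue, made up 0.399% against 0.0965%, a log2 fold change of 2.05 (unadjusted p = 0.0319, adjusted p = 0.577). WT replicate 2 held 0 of them in 13450 cells, which allows a share of up to 0.0223%. Without WT replicate 1 this class was called, but WT was then WT replicate 2 alone, with its count of 0. Plasma-like cells, which secrete antibodies, made up 0.527% against 0.171%, pericyte-like cells, which wrap capillaries, 0.450% against 0.168%, and alveolar fibroblast-like cells 3.11% ± 1.94 against 1.35% ± 0.0621. Surfactant-producing alveolar type 2-like cells made up 2.17% of GAL replicate 1 and 0.121% of GAL replicate 2, against a WT mean of 0.400% ± 0.0932.

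Of the main classes, T-like cells made up 16.6% ± 4.14 in GAL and 19.1% ± 2.99 in WT, B-like cells 12.6% ± 2.59 and 17.4% ± 6.87, and alveolar macrophage-like cells 9.97% ± 0.509 and 12.7% ± 2.16. General capillary-like endothelial cells made up 7.74% ± 2.26 and 6.09% ± 0.308, neutrophil-like cells 6.39% ± 5.21 and 6.40% ± 0.507, and interstitial macrophage-like cells 4.999% ± 1.65 and 3.74% ± 2.23. NK-like cells made up 3.14% and 5.01%, and nonclassical monocyte-like cells 2.23% ± 0.137 and 3.43% ± 0.777. By edgeR 0 of 26 classes were called and 1 had an unadjusted p under 0.05; no other tool was run on shares. On simulated data, this test found a 4-fold change in 13.3% of cases at the spread measured here.

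**Figure D1:**
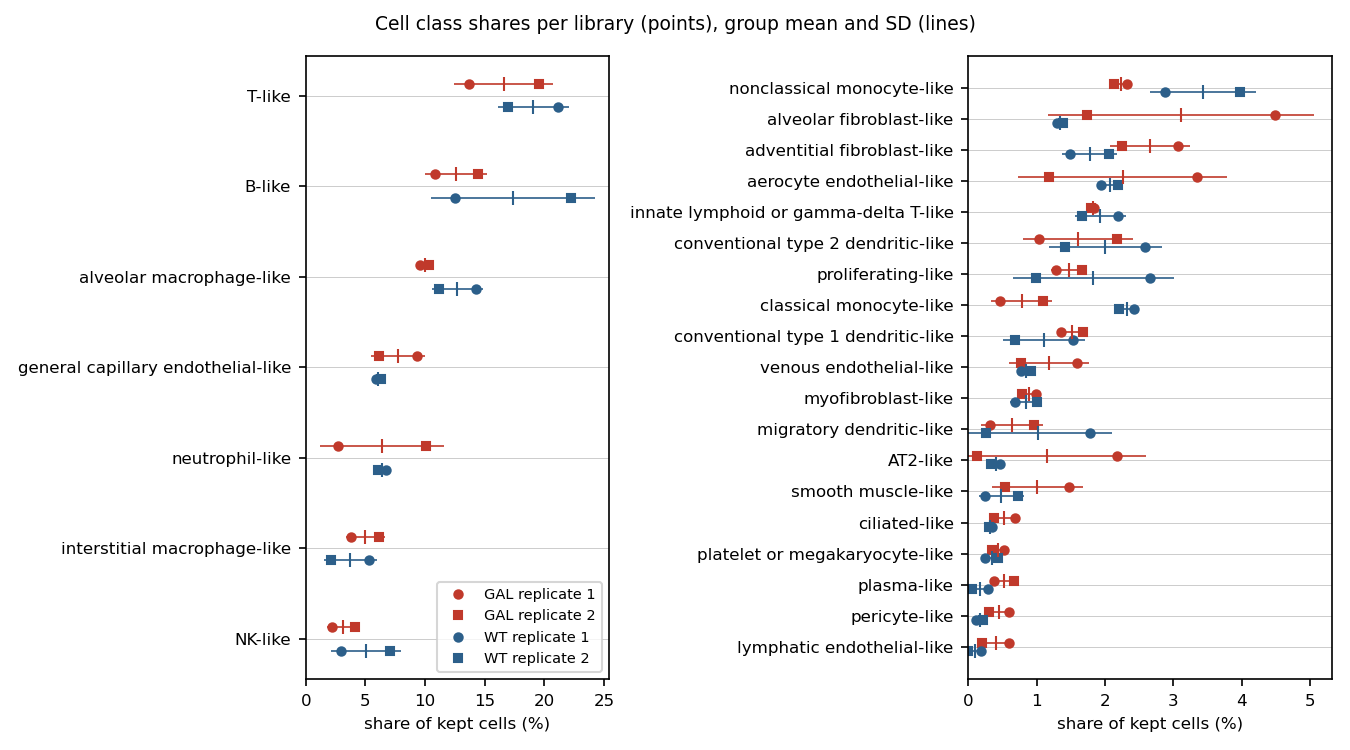
Share of kept cells (%) in each of 26 classes, with 1 point per library (GAL red, WT blue; circle replicate 1, square replicate 2) and lines for the mean and SD of each group. Classical monocyte-like cells lie lower in both GAL libraries than in both WT libraries, with a mean of 0.782% against 2.31%, and no class passed the test.

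In the whole lung, genes of pericytes and of the matrix that fibroblasts make were among those called as higher in GAL by DESeq2, together with neutrophil granule genes and genes induced by glucocorticoids. The whole-lung sum also moves with the mix of cells, so it cannot part changes within cells from changes in their numbers. By edgeR 0 of 16823 genes were called, with a smallest adjusted p of 0.717 and 1049 genes at an unadjusted p under 0.05 (824 higher, 225 lower). DESeq2 called 46 genes, 42 higher and 4 lower. Those named here were chosen after their values were seen, and their log2 fold changes are from edgeR. Of the 42, 4 were immunoglobulin segments, with log2 fold changes of up to 5.30 (Ighv1-5), the largest of all. The neuropeptide gene Nts lay at 3.67. Called as higher were the matrix genes Postn (1.82 ± 0.22), Eln (elastin, 1.53 ± 0.27), Lox (which crosslinks collagen, 1.49 ± 0.34) and Mfap4, and the pericyte genes Notch3 (1.76 ± 0.33), Pdgfrb (1.19 ± 0.23), Cox4i2, Higd1b and Agtr1a. Called as higher too were the granule genes Camp (4.86 ± 0.71; 112 and 36.9 CPM against 1.69 and 3.45) and Ltf (2.82 ± 0.65), the neutrophil surface gene Ly6g (2.35 ± 0.52), the chaperone Hspa1a (1.30 ± 0.20), the clock repressor Nr1d1 (1.07 ± 0.17), and Zbtb16 and Sult1a1. Called as lower were the RNA sensor Tlr8 (−1.14 ± 0.19), Wfdc10 (−1.36 ± 0.23) and 2 others. Among these was the immunoglobulin segment Ighv1-80 at −4.01, the largest fall, so such segments went both ways. Both GAL libraries lay on the same side of both WT libraries for 6579 genes (39.1%), where chance gives 33.3%. In the 6 main classes this share ran from 22.6% (T-like) to 32.5% (alveolar macrophage-like), below that of chance. Without GAL replicate 2, 402 genes were called by edgeR.

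Among the gene lists that passed in the whole lung, matrix genes had the highest median. Of the 28 lists, 5 passed as higher and 12 as lower by camera with a preset correlation. With an estimated correlation 0 passed, and by fry 0. These last 2 tests were not tried on simulated data, so failing them leaves a list undecided. Over all genes tested 0 members of any list were called. The 30 extracellular matrix genes had a median of 1.03, Col1a1 at 1.23 ± 0.30 among them. Of these genes, 28 were positive and 18 lay apart from WT, where chance gives 33.3% and all genes 39.1%. Adjusted over the list alone 2 were called. The camera adjusted p was 1.9e-16, and 0.569 with an estimated correlation, the value for each of the 17 lists that passed. The 13 mitochondrial DNA transcripts, the genes of the respiratory chain that mitochondria encode, had a median of 0.28 and 13 positive members (adjusted p = 0.00266), led by mt-Nd3 (1.41 ± 0.38) and mt-Co3 (0.56 ± 0.22). The 14 glucocorticoid response genes had a median of 0.34 (adjusted p = 0.00362), with Zbtb16 at 2.08 ± 0.48, Sult1a1 at 1.79 ± 0.37, Lcn2 at 1.13 ± 0.31 and Fkbp5 at 0.77 ± 0.26. The 18 endothelial activation genes had a median of 0.36 (adjusted p = 0.00564; Angpt2 0.95, Edn1 0.53, Plvap 0.81), and the 24 immediate early genes, which cells switch on within minutes of a stimulus, one of 0.23 (adjusted p = 0.0138; Ccn1 1.16, Egr1 0.71). Beyond the matrix list, 0 members of these lists were called adjusted over the list alone.

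Lists that fell in the whole lung covered energy metabolism, sterol synthesis, protein folding and immune functions, with small medians. Immune classes held a mean of 64.7% of GAL and 78.5% of WT cells, and the whole-lung sum also moves with this mix. How much of each fall comes from the mix cannot be told from the sum. Nuclear oxidative phosphorylation genes had a median of −0.22 with 0 of 35 positive (adjusted p = 0.000116; Cox5a −0.47), and cytosolic ribosomal proteins −0.13 with 0 of 42 positive (adjusted p = 0.00266; Rps6 −0.31). Cell cycle genes lay at −0.29 (21 members; adjusted p = 0.000696; Pclaf −0.72), cholesterol synthesis at −0.28 (16 members; adjusted p = 0.00156; Cyp51 −0.71, Msmo1 −0.65) and glycolysis at −0.17 (17 members; adjusted p = 0.0355; Eno1 −0.59). Lysosome genes lay at −0.24 (22 members; adjusted p = 0.00573; Neu1 −0.44) and the unfolded protein response, which the endoplasmic reticulum starts when proteins misfold, at −0.22 (23 members; adjusted p = 0.00624; Hyou1 −0.87, Sdf2l1 −0.71, but Chac1 0.92). Of the immune lists, lymphocyte effector genes lay at −0.33 (16 members; adjusted p = 0.0133; Klrg1 −0.85 ± 0.19), macrophage lipid genes at −0.30 (16 members; adjusted p = 0.0138; Plin2 −0.75 ± 0.18, but Apoe 0.48), MHC class I at −0.21 (15 members; adjusted p = 0.0138; Psmb8 −0.38) and MHC class II at −0.22 (11 members; adjusted p = 0.0278; H2-DMa −0.44). The 14 Leloir and galactose genes lay at −0.18 (adjusted p = 0.0278), led by the galactose-binding lectin Lgals3 (−0.76 ± 0.21), Galm (−0.33) and Akr1b3 (−0.28). Adjusted over the list alone 0 members of these 12 lists were called, and the adjusted p with an estimated correlation was 0.569 for each. The number of lists that passed was 6 without GAL replicate 1, 7 without WT replicate 1 and 7 with equal composition of the libraries.

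The other 11 lists did not pass in the whole lung. Surfactant genes had a median of 1.10 (adjusted p = 0.474), circadian clock genes 0.29 (adjusted p = 0.0787; 1 member called adjusted over the list alone), heat shock genes 0.23 (adjusted p = 0.0910; 1 member), NF-kB and inflammatory cytokines 0.21 (adjusted p = 0.0793), TGF-beta response 0.19 (adjusted p = 0.191), oxidative stress and NRF2 0.10 (adjusted p = 0.649) and fatty acid synthesis 0.04 (adjusted p = 0.973). For 4 lists median, mean and test differed in sign: nucleotide sugars and glycosyltransferases had a median of −0.01 and a mean of 0.01 (adjusted p = 0.297), p53 response −0.10 and 0.01 (adjusted p = 0.353), and interferon response (median 0.02, adjusted p = 0.960) and hypoxia (median 0.02, adjusted p = 0.971) leaned lower in the test. With an estimated correlation these 11 lists had adjusted p-values from 0.569 to 0.986.

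Marker lists of stromal, endothelial and some epithelial types rose in the whole lung, and those of several immune types fell, as measured from RNA rather than cell numbers. These lists were tested by camera with the preset correlation alone. Markers of 1 type can move together with its share of cells, so the p-values below may be far too small. By cells, GAL replicate 1 stood apart, with 28.3% in endothelial, epithelial and stromal classes against 14.4% in GAL replicate 2. Pericyte markers had a median of 1.76 (adjusted p = 1.8e-23), alveolar type 1 markers 2.21 (adjusted p = 0.00556; at clustering resolution 2.0 their cluster held 235 and 4 GAL cells and 23 and 13 WT cells), alveolar fibroblast 1.13 (adjusted p = 1.6e-05), smooth muscle 1.06, lymphatic endothelial 0.99, venous endothelial 0.83, plasma 0.82, ciliated 0.74, myofibroblast 0.72, general capillary 0.61, adventitial fibroblast 0.58, aerocyte 0.53 and arterial 0.23. Alveolar macrophage markers fell, with a median of −0.61 (adjusted p = 4.4e-07), as did those of NK (−0.68), B (−0.37), proliferating (−0.32) and type 2 dendritic cells (−0.31). Not passing were alveolar type 2 (1.38), mesothelial (1.45), Schwann (1.04), platelet (0.61), interstitial macrophage (0.35), erythroid (0.26), neutrophil (0.21, with a test that leaned lower), plasmacytoid dendritic (0.05) and innate lymphoid markers (−0.00). The same held for T (−0.14), classical monocyte (−0.21), nonclassical monocyte (−0.25), type 1 dendritic (−0.25), migratory dendritic (−0.29), basophil or mast (−0.58) and club cell markers (−0.69).

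In T-like cells, the effector cytokine gene Ifng and mitochondrial transcripts lay higher in GAL, and genes of cell division and sterol synthesis lower. By edgeR 0 of 10832 genes were called, 107 had an unadjusted p under 0.05, and DESeq2 called 0; 14 were called without GAL replicate 1 and 36 without GAL replicate 2. Of 28 lists, 8 passed as higher and 4 as lower, each with an adjusted p from 0.596 to 0.791 with an estimated correlation, and 0 members were called over all genes tested. Higher were matrix genes, most of which T cells do not make (median 1.13 over 19 members, with Col1a1 at 1.72 ± 0.50 and Mfap4 at 1.43 ± 0.44). Mitochondrial transcripts rose too (0.38, with mt-Nd3 at 1.38 ± 0.31), and 1 of 13 was called adjusted over the list alone. Heat shock genes also rose (0.36, with Dnajb1 at 0.45 ± 0.25). Lymphocyte effector genes lay at 0.11, with 1 of 16 called adjusted over the list alone and Ifng at 1.10 ± 0.21 (41.9 and 39.3 CPM against 19.8 and 18.1), beside endothelial activation (0.25), glucocorticoid response (0.18), NF-kB (0.11; Cxcl1 0.87) and immediate early genes (0.07; Ccn1 1.02). Lower were cell cycle (−0.40; Birc5 −1.13 ± 0.51), cholesterol synthesis (−0.23; Idi1 −0.49 ± 0.21), nuclear oxidative phosphorylation (−0.12) and ribosomal proteins (−0.10). Of the marker lists of other types, 12 passed. General capillary (0.75), aerocyte (0.64), venous (0.78), alveolar fibroblast (0.48), adventitial fibroblast (0.46), smooth muscle (0.72), alveolar type 2 (1.24) and neutrophil markers (0.36) were higher. Erythroid (−1.37), alveolar macrophage (−0.66), B (−0.35) and proliferating cell markers (−0.43) were lower.

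B-like cells of GAL had lower values of the enzymes of sterol synthesis and of chaperones of the endoplasmic reticulum, and higher values of mitochondrial transcripts. Among 9763 genes edgeR called 0, 167 had an unadjusted p under 0.05, and DESeq2 called 0; the count was 14 without GAL replicate 1 and 49 without GAL replicate 2. Cholesterol synthesis fell by a median of −0.45, with Cyp51 at −0.65 ± 0.25 and Fdps at −0.63 ± 0.26. Of its 16 members, 1 was positive and 10 lay apart, where chance gives 33.3% and all genes of the class 26.7%. The camera adjusted p was 2.0e-09, and 0.682 with an estimated correlation. The unfolded protein response fell (−0.27, 20 members; adjusted p = 3.4e-08, and adjusted p = 0.376 with an estimated correlation), with Sdf2l1 at −0.87 ± 0.26, Hyou1 at −0.72 and Xbp1, a regulator of antibody secretion, at −0.46, as did nuclear oxidative phosphorylation (−0.14; adjusted p = 0.682 with an estimated correlation). Mitochondrial transcripts rose (0.52, 13 members; adjusted p = 0.319 with an estimated correlation), with 8 called adjusted over the list alone and 0 over all genes tested. Matrix genes rose too (1.14, 14 members, 5 called adjusted over the list alone; Sparc 1.33 ± 0.29; adjusted p = 0.682 with an estimated correlation), beside general capillary markers at 0.49, alveolar and adventitial fibroblast markers at 1.02 and 0.57, and erythroid, alveolar macrophage and plasmacytoid dendritic markers at −1.20, −0.65 and −0.83.

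Alveolar macrophage-like cells of GAL, the phagocytes of the air spaces, had higher values of immediate early, cytokine and glucocorticoid-induced genes and lower values of the unfolded protein response. Of 11817 genes tested, edgeR called 0 and 448 had an unadjusted p under 0.05, while DESeq2 called 9 as higher, among them, chosen after their values were seen, S100a8 (1.09 ± 0.12) and S100a9 (1.70 ± 0.28), which neutrophils make in bulk, Pdgfb (1.57 ± 0.24), Fkbp5 and mt-Nd3. Leaving out GAL replicate 1 or GAL replicate 2 gave 8 or 19 edgeR calls. A term for the other pairing of the libraries, added after the results were seen, gave 54 (44 higher, 10 lower). Immediate early genes had a median of 0.41 (23 of 24 positive, 16 apart where chance gives 33.3%; Ccn1 1.30 ± 0.29, Egr1 0.67 ± 0.23, Fos 0.47 ± 0.18), NF-kB genes 0.51 (21 of 22 positive; Lcn2 1.17 ± 0.41, Nfkbiz 0.93 ± 0.33) and glucocorticoid response genes 0.29 (2 of 14 called adjusted over the list alone; Fkbp5 1.15 ± 0.22, Zbtb16 2.46 ± 0.58). Matrix genes (1.31), endothelial activation (0.47) and mitochondrial transcripts (0.38) passed as higher, and the unfolded protein response as lower (−0.35; Creld2 −0.99 ± 0.26). These 7 lists had, with an estimated correlation, adjusted p-values from 0.587 to 0.821, and 0 members were called over all genes tested. The class joins cluster 3 with cluster 6, which is led by the stimulation genes Ereg, Inhba, Il1a, Tnf and Cxcl3. Cluster 6 gave 50.4% of the GAL cells and 29.5% of the WT cells of the class, with 211, 878, 688 and 280 cells per library, so it did not follow the groups. Markers of 3 endothelial types lay at 0.93 to 1.13 in this class, those of 2 fibroblast types at 1.06 and 0.72, neutrophil markers at 0.40, interstitial macrophage markers at 0.37, nonclassical monocyte markers at 0.28 and erythroid markers at −0.93.

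General capillary-like endothelial cells of GAL had higher values of genes that glucocorticoids induce, with lower values of hypoxia, interferon and protein folding genes. By edgeR 0 of 9876 genes were called (316 at an unadjusted p under 0.05, smallest adjusted p 0.0666), and DESeq2 called 1, Zbtb16, a transcription factor that glucocorticoids induce (1.63 ± 0.24; 356 and 269 CPM against 112 and 91.3). Leaving out a library gave more calls, 113 without GAL replicate 1, 97 without GAL replicate 2 and 21 without either WT library. The 12 glucocorticoid response genes had a median of 0.42, with 4 called adjusted over the list alone: Zbtb16, Sult1a1 (1.53 ± 0.28), Fkbp5 (1.61 ± 0.34) and Tsc22d3 (0.67 ± 0.23). Mitochondrial transcripts (0.31) and matrix genes (0.35; Mfap4 2.08 ± 0.52) also passed as higher, each with 1 member called adjusted over the list alone. Hypoxia genes fell (−0.09; Vegfa −0.86 ± 0.23, Ndrg1 −0.80 ± 0.25; 1 called adjusted over the list alone), as did interferon (−0.09; Gbp2 −0.55 ± 0.25), immediate early (−0.20) and unfolded protein response genes (−0.21; Hyou1 −0.65). With an estimated correlation the adjusted p of these 7 lists was 0.755, and erythroid and alveolar macrophage markers lay at −1.30 and −0.94, with aerocyte and alveolar fibroblast markers at 0.28 and 0.35.

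Neutrophil-like cells of GAL had higher values of the neutrophil surface gene Ly6g and lower values of interferon-induced genes. EdgeR called 0 of 5818 genes there and 171 had an unadjusted p under 0.05, while DESeq2 called 3: Ly6g (2.37 ± 0.34; 215 and 135 CPM against 27.9 and 38.8), Lcn2 (1.88 ± 0.38) and Ifitm6 (1.69 ± 0.36). The granule genes Camp (5.54 ± 0.88; 7586 and 848 CPM against 64.8 and 115) and Ltf (4.71 ± 0.82), chosen after their values were seen, were not called. The class joins cluster 5 with the small cluster 37, which is led by Ngp, Camp and Ltf and held 27, 6, 1 and 5 cells (GAL replicate 1, GAL replicate 2, WT replicate 1, WT replicate 2). It held 99.98% and 99.8% of the Camp UMIs of the class in GAL. The same shares were 76.4% and 10.2% of those of Ly6g, 81.8% and 17.6% of those of Lcn2 and 88.1% and 31.7% of those of Ifitm6. In cluster 5 alone Ly6g had 64.8 and 114 UMIs per 1e6 in GAL against 28.8 and 30.9 in WT, and Lcn2 1085 and 1499 against 818 and 865. Ifitm6 overlapped there, at 118 and 235 against 183 and 146. Camp had 1.85 and 1.38 there against 65.0 and 0.791. Interferon response genes fell (−0.36, 18 members; Irgm1 −1.01 ± 0.42), as did MHC class I (−0.26; Tap1 −0.98 ± 0.35) and p53 response genes (−0.21; Ccng1 −1.14 ± 0.34). Glycolysis genes rose (0.32; Gapdh 0.80 ± 0.28, Hk1 0.94 ± 0.39), as did oxidative stress genes (0.16; Gpx3 1.48 ± 0.36), mitochondrial transcripts (0.29) and matrix genes (0.99; Bgn 1.45 ± 0.39). The oxidative stress and matrix lists each had 1 member called adjusted over the list alone and 0 over all genes tested, and with an estimated correlation the adjusted p of the 7 lists was 0.739 or 0.808. Without GAL replicate 1 the edgeR count was 66, and without GAL replicate 2 it was 117; GAL replicate 1 gave 2.71% of its cells to this class and GAL replicate 2 gave 10.1%. Classical monocyte markers passed as higher in it (0.34).

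Interstitial macrophage-like cells of GAL had higher chemokine and glucocorticoid-induced genes, with lower values of cytotoxic genes led by the NK marker Gzma. Of 9961 genes edgeR called 0, 137 had an unadjusted p under 0.05, and DESeq2 called 0. NF-kB genes rose (0.32, 22 members; Ccl4 1.16 ± 0.37, Tnf 0.80 ± 0.34), with glucocorticoid response (0.26; Fkbp5 1.53 ± 0.58, Zbtb16 2.60 ± 0.99), endothelial activation (0.44; Edn1 1.01 ± 0.35), mitochondrial transcripts (0.45) and matrix genes (0.49; Eln 1.14). Lymphocyte effector genes fell (−0.76, 7 members), with the granzyme gene Gzma at −2.01 ± 0.32 and called adjusted over the list alone. Gzma lay below 0 in 13 of the 15 classes in which it was tested (median −0.50), so its fall is not particular to this class. NK-like cells made up 3.14% of GAL cells and 5.01% of WT cells, and whether this Gzma RNA came from the macrophages was not tested. The unfolded protein response (−0.27, with Creld2 at −0.96 ± 0.40) and nuclear oxidative phosphorylation (−0.19) fell too. For these 8 lists the adjusted p with an estimated correlation ran from 0.677 to 0.900, and capillary markers lay at 0.59 in the class.

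Among the 22 classes the monocyte-like ones had the most genes at an unadjusted p under 0.05, with inflammatory cytokine genes and the anti-inflammatory cytokine Il10 higher in GAL. In the classical monocyte-like class edgeR called 42 of 6514 genes, 35 higher and 7 lower, and DESeq2 26; 599 had an unadjusted p under 0.05. The following genes were chosen after the calls were seen, by the rule of the main classes. Il10 rose most, by 4.72 ± 0.41 (adjusted p = 6.6e-05), from 3.58 and 3.64 CPM in WT to 114 and 88.5 CPM in GAL. Next came Mir155hg (3.77 ± 0.68), host of an inflammatory microRNA, Spic (3.62 ± 0.65), a factor of iron-recycling macrophages, the costimulatory ligand Tnfsf9 (3.24 ± 0.41) and the acute-phase gene Saa3 (3.19 ± 0.51). Among called genes with a mean of at least 20 CPM, Gpat3 (−2.00 ± 0.42), Rrp1b (−1.71 ± 0.36), the cytokine Osm (−1.56 ± 0.30), Mindy1 (−1.41 ± 0.29) and the cAMP-responsive factor Crem (−1.39 ± 0.27) fell most. Below that level Vdr was called with a larger fall, at −4.32 ± 0.87 (3.45 and 0 CPM in GAL against 25.1 and 23.3 in WT). The class held 51 and 118 cells in GAL and 301 and 297 in WT. Without each of GAL replicate 1, GAL replicate 2 and WT replicate 1 in turn, the count was 238, 60 and 220, with 41, 22 and 41 of the 42 genes among them; with adjustment over all classes together only Il10 was called, with sums thinned to the smallest library 0 genes were, and at clustering resolution 2.0 2 genes were.

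NF-kB target genes, which code for cytokines and their feedback inhibitors, rose as a list in both monocyte-like classes. In the classical class 21 of 22 were positive, with a median of 1.64. Of the list, 18 lay apart, where chance gives 33.3% and all genes of the class 37.6%. For some genes the libraries of a group differed widely, with WT replicate 1 near GAL replicate 1. Il1b had 1915 and 3476 CPM in GAL (replicates 1 and 2) against 1501 and 500 in WT. Nfkbiz had 314 and 587 against 162 and 33.5. The groups lay further apart for Icam1, with 135 and 174 against 46.6 and 19.6. Over all genes tested 6 were called, and adjusted over the list alone 20 were. Among the 20 were Cxcl1 (3.11 ± 0.48), Icam1 (2.27 ± 0.35), Tnf (2.31 ± 0.37) and Saa3. The camera adjusted p was 2.5e-33, and 0.611 with an estimated correlation. In the nonclassical class, the patrolling monocytes of the blood, edgeR called 0 of 6618 genes and DESeq2 called 49. By edgeR 649 had an unadjusted p under 0.05, with a smallest adjusted p of 0.0531. A term for the other pairing of the libraries, added after the results were seen, gave 96 edgeR calls in this class (91 higher, 5 lower). There 20 of 20 NF-kB genes were positive, with a median of 1.62, 18 called adjusted over the list alone and 0 over all genes tested (Tnf 2.60 ± 0.40, Cxcl1 2.11 ± 0.33, Cxcl2 2.10 ± 0.36, Il1a 2.87 ± 0.50; adjusted p = 2.6e-31, and adjusted p = 0.337 with an estimated correlation). Oxidative stress genes passed as higher in both classes (medians 0.08 and 0.26), with Slc7a11 at 1.63 and 2.15 and Sod2 at 1.52 and 1.45, as did immediate early genes (0.36 and 0.46; Egr1 1.49 and 1.38) and mitochondrial transcripts (0.69 and 0.75). MHC class II genes rose in the classical class (0.75; Cd74 0.83 ± 0.19, H2-Aa 0.89 ± 0.21), and cholesterol synthesis fell in the nonclassical class (−0.58; Msmo1 −0.93 ± 0.23). These further lists had, with an estimated correlation, an adjusted p of 0.611 in the classical class and from 0.263 to 0.271 in the nonclassical class. Markers of nonclassical monocytes lay at 0.75 and those of type 2 dendritic cells, Tnfsf9 among them, at 0.60 in the classical class.

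**Figure D2:**
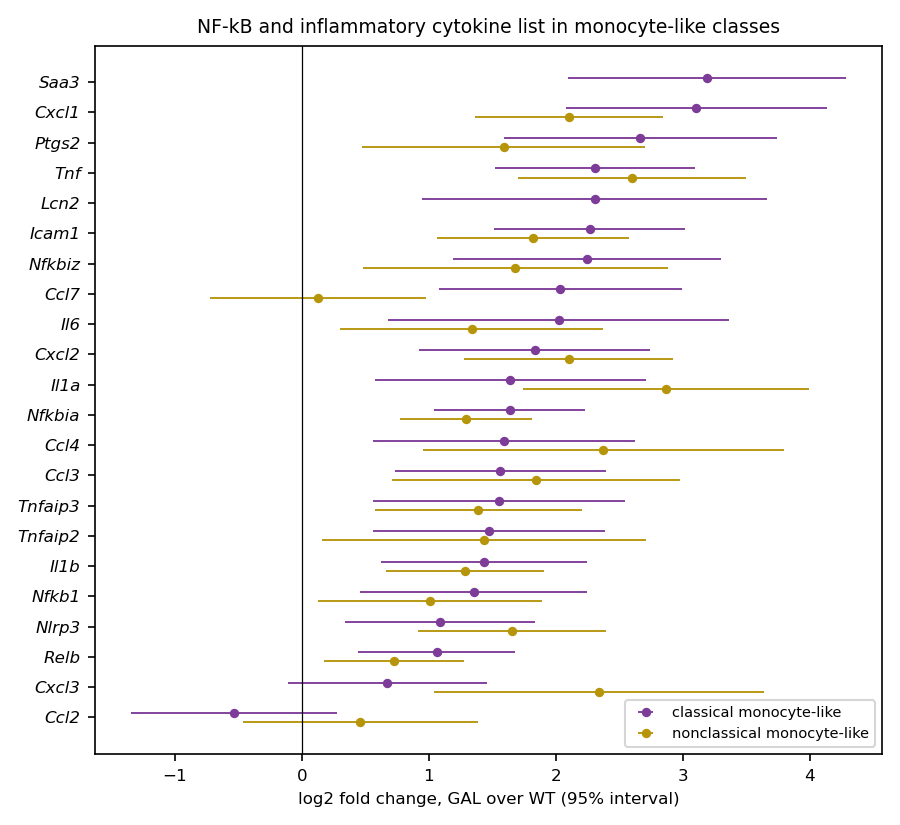
Log2 fold change (GAL over WT) with 95% interval of each NF-kB list gene in the classical and the nonclassical monocyte-like class. In the classical class 21 of 22 genes lie above 0, and in the nonclassical class 20 of 20.

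Aerocyte-like endothelial cells, the large capillary cells used for gas exchange, had the only other edgeR calls, 2 of 7965 genes (297 at an unadjusted p under 0.05; DESeq2 called 1). Both genes, chosen after their values were seen, are glucocorticoid response genes: Zbtb16 rose by 1.47 ± 0.21 (262 and 266 CPM against 95.7 and 94.2) and Sult1a1, a sulfotransferase, by 2.48 ± 0.37 (55.0 and 66.5 against 5.89 and 13.6), each with an adjusted p of 0.0223. Without WT replicate 1 neither was called, at adjusted p-values of 0.266 and 0.178. The 10 glucocorticoid response genes had a median of 0.38, with 3 called adjusted over the list alone (adjusted p = 1.2e-09, and adjusted p = 0.646 with an estimated correlation). Markers of general capillary cells (0.38), in which Zbtb16 was higher too, and of alveolar fibroblasts (0.41) passed as higher in this class.

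Across the 22 classes, mitochondrial transcripts rose in each class, matrix genes in 14 of the 17 in which they could be tested, and glucocorticoid response genes in 12 of 22, while the unfolded protein response fell in 11 of 22. These calls are by camera with a preset correlation. With an estimated correlation each of the 4 lists passed in 0 classes. The mitochondrial medians ran from 0.23 to 0.75, and 70 members were called adjusted over the list alone; the list passed in 18, 22, 22 and 17 classes when GAL replicate 1, GAL replicate 2, WT replicate 1 and WT replicate 2 were left out. Glucocorticoid response genes passed in 1 class without GAL replicate 1 and in 8 without WT replicate 2, and in the venous class their median was −0.03 although the test was higher. Zbtb16 was higher in both GAL libraries than in both WT libraries in 14 of 18 classes (median 1.44). The same held for Sult1a1 in 10 of 13 (1.53) and for Fkbp5 in 11 of 17 (1.02). Within a single class chance sets the groups apart, in either direction, for 33.3% of genes. All classes come from the same 4 libraries, so these counts of classes are not independent trials. The median of the unfolded protein response was below 0 in 22 of 22 classes, and the chaperone Hsp90b1 was lower in both GAL libraries in 19 of 22 (median −0.35) and Creld2 in 16 of 20 (−0.50); the list passed in 6 classes without GAL replicate 2 and in 6 without WT replicate 2. In adventitial fibroblast-like cells it fell by −0.53, with 6 of 20 members called adjusted over the list alone (Hyou1 −1.23 ± 0.26, Creld2 −1.11 ± 0.24; adjusted p = 0.725 with an estimated correlation). Matrix genes passed in 5 classes without GAL replicate 1.

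Other lists passed in some classes. Immediate early genes passed as higher in 9 classes and lower in 3, NF-kB genes in 7 and 1, heat shock genes in 6 and 1, and endothelial activation genes in 5 and 1. Without GAL replicate 1 these counts were 7 and 6, 11 and 0, 6 and 4, and 1 and 2. Without WT replicate 1 they were 6 and 3, 14 and 1, 3 and 1, and 4 and 0. In the reported fit the NF-kB test leaned higher in 17 classes and lower in 5. Without GAL replicate 1, GAL replicate 2, WT replicate 1 and WT replicate 2 it leaned higher in 17, 13, 18 and 9. In the same order it leaned lower in 5, 9, 4 and 13, so its direction hung on WT replicate 2. Heat shock genes had their highest median in innate lymphoid-like cells (0.76, 7 of 12 called adjusted over the list alone; Hspa1a 2.04 ± 0.40, Hspa1b 3.06 ± 0.75), followed by NK-like cells (0.66), and their lowest in ciliated-like cells (−0.52). Cholesterol synthesis fell in 6 of 19 classes, with medians of −0.75 in type 2 and −0.65 in type 1 dendritic-like cells. Interferon response and nuclear oxidative phosphorylation genes each fell in 5 classes, MHC class I in 4, and cell cycle and p53 response genes in 2 each. The first 3 also hung on single libraries: without WT replicate 1 they passed as higher in 9, 2 and 4 classes and as lower in 3, 1 and 1. Without WT replicate 2 they passed as lower in 11, 11 and 9. Oxidative stress genes rose in 3 classes, glycolysis in 2, and surfactant, lysosome and TGF-beta response genes in 1 each. Surfactant genes passed as lower in 9 of 15 classes without GAL replicate 1 and as higher in 17 of 17 without GAL replicate 2. Ribosomal proteins rose in 2 and fell in 2, MHC class II rose in 3 and fell in 2, hypoxia rose in 1 and fell in 1, and lymphocyte effector genes rose in 1 and fell in 2. Nucleotide sugars and glycosyltransferases fell in 1 class, the smooth muscle-like cells (−0.45; Cmas −1.53 ± 0.55), in which pericyte markers were higher (0.55). They passed in 0 classes when any library but GAL replicate 2 was left out. Leloir, fatty acid synthesis, circadian clock and macrophage lipid genes passed in 0. Leaving out a library changed this for clock genes (higher in 5 classes without GAL replicate 1, higher in 3 and lower in 2 without WT replicate 1), macrophage lipid genes (lower in up to 5, without WT replicate 2, and higher in up to 3, without GAL replicate 2), fatty acid synthesis (higher in 2 without WT replicate 1) and Leloir genes (lower in 1 without GAL replicate 1). With an estimated correlation 0 of the lists passed in any class, and the smallest adjusted p was 0.263.

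**Figure D3:**
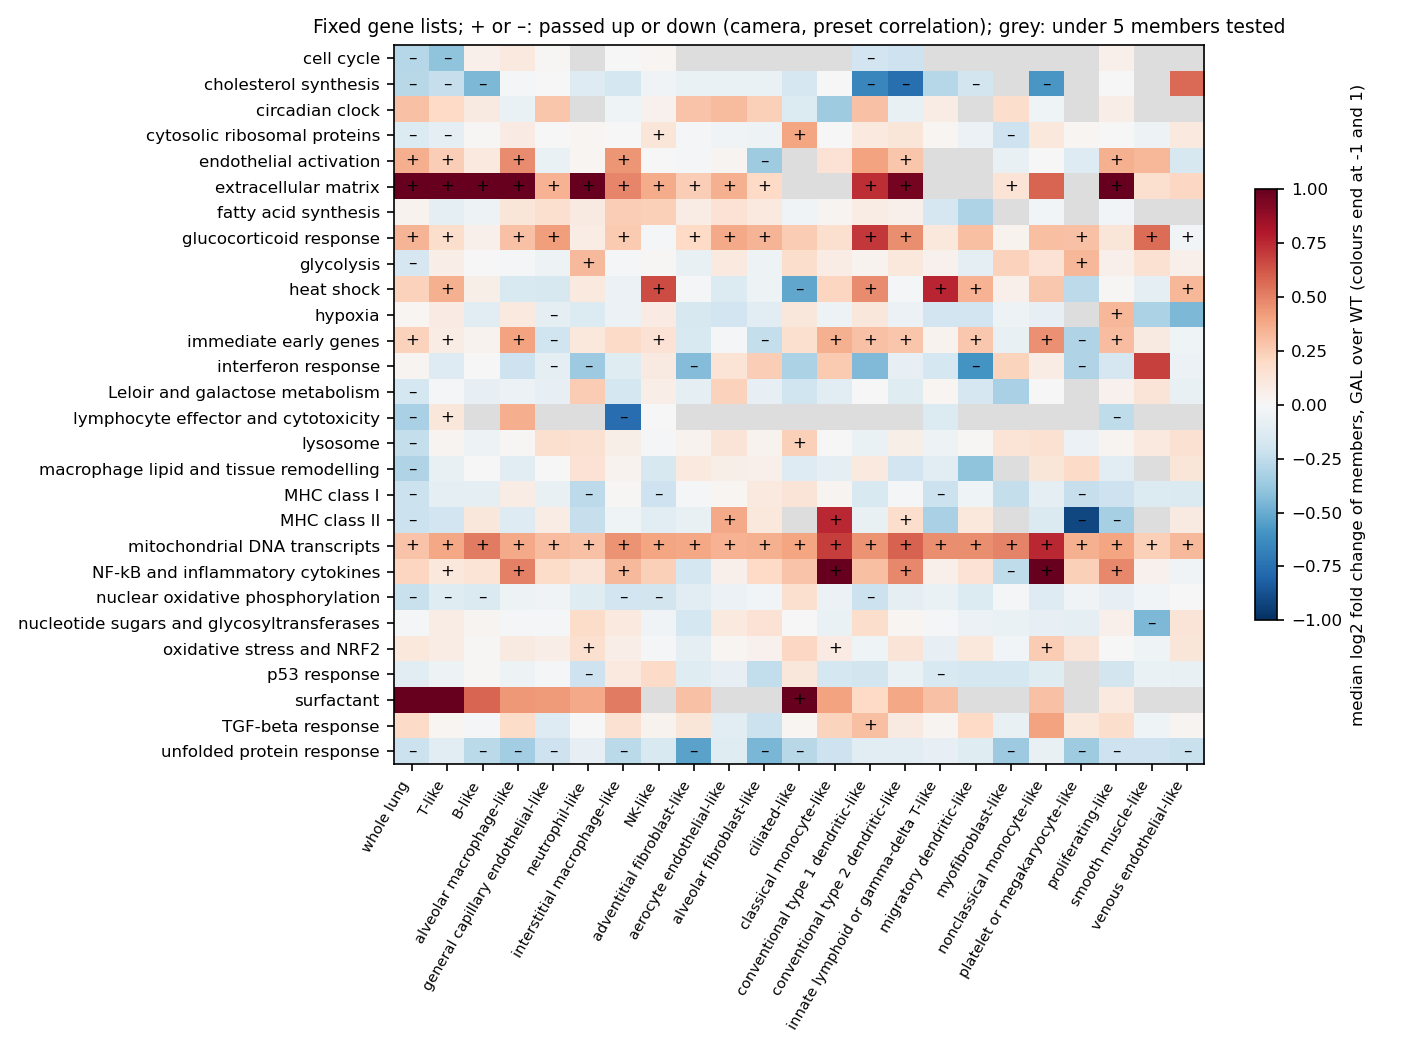
Median log2 fold change (GAL over WT, colour from −1 to 1) of the measured members of 28 gene lists in the whole lung and 22 classes, with + or − where the list passed camera with a preset correlation and grey where fewer than 5 members were measured. Mitochondrial transcripts are higher in each of the 22 classes, and the unfolded protein response has a median below 0 in each of them.

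The mitochondrial gene mt-Nd3, singled out after its values were seen, was higher in both GAL libraries than in both WT libraries in 22 of 22 classes. It encodes a subunit of complex I of the respiratory chain and lies on the mitochondrial genome from 9459 to 9806 (ENSMUSG00000064360, 348 nt). In the whole lung it had 224 and 189 CPM in GAL and 105 and 50.3 CPM in WT, a log2 fold change of 1.41 ± 0.38 with an edgeR adjusted p of 0.717. Its class values ran from 1.15 to 2.12, with a median of 1.47, against 0.67 for mt-Co3 and 0.51 for mt-Cytb.

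**Figure D4:**
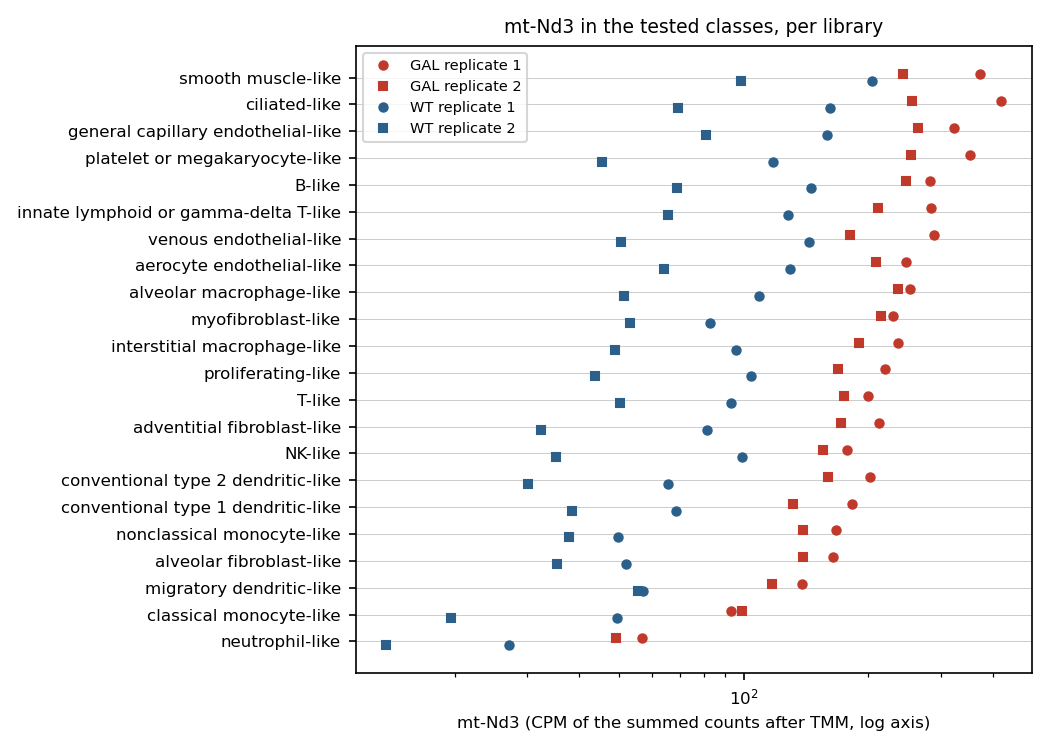
CPM of mt-Nd3 (log axis) in each library and in each of 22 classes, with GAL in red and WT in blue. Both GAL libraries lie above both WT libraries in 22 of 22 classes.

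The libraries also differed in a way the groups do not give. Comparing GAL replicate 1 and WT replicate 2 with GAL replicate 2 and WT replicate 1 called 2704 genes over the 22 classes by edgeR, against 44 for GAL with WT and 48 for the remaining split. Of these, 1252 lay in T-like cells and 766 in interstitial macrophage-like cells, and in T-like cells the cluster led by the activation genes Tnfsf8, Ctla4, Tnfrsf4 and Icos held 390, 1142, 1642 and 436 cells (GAL replicate 1, GAL replicate 2, WT replicate 1, WT replicate 2). With a term for this pairing, added after the results were seen, edgeR called 283 genes between GAL and WT in classical monocyte-like, 17 in neutrophil-like, 11 in general capillary-like, 5 in interstitial macrophage-like and 4 in T-like cells. It called 0 in B-like cells and in the whole lung. The labels name no batch, sex or age that would part the libraries this way. Sex-linked genes gave the same sex for all 4 libraries.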

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

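The term for the libraries' other pairing and the separate count for classical monocyte-like cells were chosen only after the results were seen. Counts below are genes called by edgeR, with those of the reported fit first; the cause of a change was not tested unless stated. Relative log expression factors, doublets kept and at most 10% mitochondrial UMIs moved 0 of the class and whole-lung counts by more than 1.5 times.

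DESeq2 gave 46 whole-lung genes in place of 0, 9 in place of 0 in alveolar macrophage-like, 1 in general capillary-like and 3 in neutrophil-like cells, 86 in place of 44 over the 16 other classes, and 26 in place of 42 in classical monocyte-like cells, 22 of them shared. Without the filter on low counts the counts were 22 (B-like), 49 (general capillary), 35 (neutrophil) and 29 (interstitial macrophage) in place of 0, 832 over the other classes and 182 in classical monocyte-like cells, the latter holding all 42 genes.

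Leaving out 1 library, where the lone sample of a group was assumed to vary like the others, gave 0 to 402 whole-lung calls (402 without GAL replicate 2). In classes it gave 0 to 36 (T-like; 14 without GAL replicate 1, 36 without GAL replicate 2), 0 to 49 (B-like; 14 and 49), 0 to 19 (alveolar macrophage; 8 and 19), 21 to 113 (general capillary; 113, 97, 21 and 21 without GAL replicate 1, GAL replicate 2, WT replicate 1 and WT replicate 2), 0 to 117 (neutrophil; 66, 117, 1 and 0) and 0 in interstitial macrophage-like cells. Over the other classes it gave 364 to 920 (920, 421, 471 and 364), and in classical monocyte-like cells 51 to 238 (238, 60, 220 and 51, of which 41, 22, 41 and 31 were among the 42). Shares ranged from 0 to 1 called class (lymphatic endothelial-like, without WT replicate 1).

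General capillary-like counts were 2 with deeper cells, 2 after thinning, 2 without genes abundant in free RNA and 1 at clustering resolution 2.0. Thinning, which removes counts, gave 3 in neutrophil-like cells, 20 over the other classes and 0 in classical monocyte-like cells, and resolution 2.0 gave 2 in the latter. Adjusting over all classes together, which tests more genes at once, left 1 call, Il10. With a term for the other pairing of the libraries the counts were 0 (whole lung), 4 (T-like), 0 (B-like), 54 (alveolar macrophage), 11 (general capillary), 17 (neutrophil), 5 (interstitial macrophage), 772 (other classes) and 283 (classical monocyte).

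Of the lists that passed, 17 in the whole lung, 46 in main classes and 93 in the other classes, 0, 0 and 0 passed with an estimated correlation and 0, 0 and 0 by fry. With equal composition of the libraries 7 whole-lung lists passed, but each library was also cut to 6842 cells, so the cause is open. Leaving out a library gave 6 to 15 whole-lung lists (6 without GAL replicate 1, 7 without WT replicate 1), 45 to 58 in main classes and 91 to 118 in the others.

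Galt, which was not called in any setting, changed sign in some. Its whole-lung log2 fold change of 0.0392 became −0.0372 with equal composition and ran from −0.0645 to 0.11 when a library was left out. Leaving out a library also gave it −0.367 to 0.206 in T-like, −0.918 to 0.259 in B-like, −0.0859 to 0.00929 in alveolar macrophage-like, −0.00799 to 0.306 in alveolar fibroblast-like, −0.0111 to 0.303 in type 2 dendritic-like and −0.640 to 0.120 in proliferating cells. The genes named for their calls in the classical monocyte-like and aerocyte-like classes, Vdr apart, kept their sign in every setting tried that gave a value. They lost their call in 41 cases, 11 of them under adjustment over all classes together. Vdr and clustering at resolution 2.0 were left out of this check. At that resolution only 2 of the 42 calls of the classical monocyte-like class stayed.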

Other observations

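The tests of cell damage, of a mitochondrial variant and of free RNA of stromal cells were chosen only after the results they weigh were seen. Stromal and rarer immune classes added changes of their own. In adventitial fibroblast-like cells the glucocorticoid-induced leucine zipper gene Tsc22d3 lay at 1.33 ± 0.21, with Zbtb16 at 1.39 ± 0.32 and 3 of 14 list members called adjusted over the list alone, and interferon genes fell by a median of −0.43 (Irf7 −1.10 ± 0.43). Alveolar fibroblast-like cells had lower chaperones (unfolded protein response −0.46; Manf −0.94 ± 0.24, Hspa5 −0.64 ± 0.20) and, within the matrix list, higher Mfap4 (0.98 ± 0.27) and Eln (0.76 ± 0.21) but lower Loxl2 (−1.03 ± 0.26), beside general capillary markers at 0.61 and aerocyte markers at 0.28. Myofibroblast-like cells were the only class in which NF-kB genes passed as lower, with a median of −0.25, 2 of 14 called adjusted over the list alone, and Il6 at −1.14 ± 0.28 and Tnfaip3 at −1.02 ± 0.37, beside smooth muscle markers at 0.74. With an estimated correlation the adjusted p of these lists ran from 0.679 to 0.764, and by edgeR 0 genes were called in the 3 classes, with 344, 426 and 167 genes at an unadjusted p under 0.05 and 1, 1 and 0 called by DESeq2.

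In type 2 dendritic-like and proliferating cells NF-kB genes were higher too, by smaller medians than in the monocyte-like classes. No test compared these classes with the monocytes. Type 2 dendritic-like cells had higher chemokine genes (NF-kB median 0.48, 19 of 19 positive; Ccl4 1.18 ± 0.27, Ccl7 1.89 ± 0.50), higher Ccl5 and lower Plac8 by DESeq2 (1.91 ± 0.33 and −1.52 ± 0.32, chosen after their values were seen) and lower sterol enzymes (Idi1 −1.02 ± 0.30), beside neutrophil markers at 0.26 and type 1 dendritic markers at −0.18. Proliferating cells of mixed lineage had higher NF-kB genes (0.48, 20 of 20 positive; Tnf 1.41 ± 0.19, called by DESeq2) beside interstitial macrophage markers at 0.88, neutrophil markers at 0.46 and type 1 dendritic markers at −0.66, so their mixture of lineages also differed. In migratory dendritic-like cells interferon genes fell (−0.60; Irf7 −1.60 ± 0.55), and in ciliated-like cells, which sweep mucus along the airway, ribosomal protein genes rose (0.40, 40 of 42 positive). Platelet-like cells had lower MHC class II genes (−0.91; H2-Aa −1.40 ± 0.77). With an estimated correlation the adjusted p of these lists ran from 0.290 to 0.810.

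Transcripts of mt-Nd3 lay higher in both GAL libraries in 22 of 22 classes. Damaged cells that lose cytoplasmic RNA keep all mitochondrial transcripts alike. The other transcripts rose too, by class medians from 0.20 to 0.71, and damage as a cause of that shared rise was not tested. Yet mt-Nd3 exceeded the median of the others by 1.08 (median over classes, range 0.68 to 1.78). Its choice after the values were seen favours a large excess. With that limit, the excess argues against damage as its cause. Better recovery of short transcripts was not seen either: 55 nuclear genes with transcripts of at most 600 nt had a median of −0.149 (quartiles −0.268 to 0.00250), and 0 of them lay apart as higher. WT replicate 1 had 2.05 times the level of WT replicate 2 (median over classes, range 1.03 to 2.84), so a variant of the GAL mice alone is not the whole cause of the differences between libraries. A difference in library preparation that the labels do not give, and the genotype itself, stay open and may each contribute, and neither was tested.

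NF-kB genes were higher in monocyte-like cells of GAL. Drawing 51 cells per library left the classical median at 1.63 in the middle of 20 draws (1.43 to 2.53). The rise therefore held at equal cell numbers. Every draw held the same 51 cells of GAL replicate 1 and only 16 to 18 of the 22 members. The draws cannot tell whether so few cells make its values unstable. Summing both monocyte classes gave 1.63 with 21 of 22 positive. An exchange of cells between these classes alone would leave their sum unchanged, so it is not the sole cause. Nonclassical monocyte markers still lay at 0.75 in the classical class, and at clustering resolution 2.0 only 2 of its 42 calls stayed. Admixed cells or RNA of another class, as far as their markers allow, gave at most 5.78% of the excess (type 1 dendritic-like). Stimulation during digestion, an unlabelled batch or a response of monocytes to the genotype may explain the pattern, and these were not tested against each other.

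Matrix genes, some of which immune cells make, such as the classical monocyte marker Fn1, were higher in immune classes of GAL. Their rise in 10 immune classes differed from the whole-lung rise of the same genes by a median of 0.102 (−0.42 to 0.48), which is consistent with free RNA of stromal cells. Matrix UMIs per 100 T-like cells were 92.4 and 38.0 in GAL and 25.3 and 26.4 in WT. Doublets with stromal cells stay open, since cells with 3 or more matrix UMIs held 24.3% of such UMIs in GAL T-like cells (530 of 2179), with 32.7% in GAL replicate 1 and 9.79% in GAL replicate 2, on both sides of the 25% set as the limit. Free RNA could likewise add to the matrix, capillary and erythroid values of the other immune classes.

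The 4 libraries can be split in 3 ways, too few for a share under 0.05. GAL against WT gave 44 calls over the 22 classes and 0 in the whole lung; the highest other split gave 2704 and 0. In the classical monocyte-like class the counts were 42 for GAL against WT, 0 with GAL replicate 1 and WT replicate 1 together, and 1 with GAL replicate 1 and WT replicate 2 together. The split of GAL replicate 1 and WT replicate 2 from the others therefore points to a structure of the samples, and no label names it.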
